A study of Mus musculus with 6 samples.

How the data were processed

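Total RNA had been extracted with a column kit and biotin-labelled, and was hybridised to Illumina mouse WG-6 version 2 arrays, per the labels. The labels place 3 samples in the control virus group and 3 in the IRF5-4D virus group, and the design text calls them biological replicates. Culture conditions, the share of transduced cells, any sorting on the fluorescent marker, the scan and the summary of beads into probe signals are not given in the sources used here.

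The values came in a pair of tables with the same 46237 probes. In the table deposited as non-normalized, the authors give log2 probe signals between 5.64 and 15.94, as found from the values: per array, 65.8% to 67.0% of them are the log2 of a brightness within 0.01 of a whole number. It has no background subtraction (the lowest value is 50 brightness units), and its array medians of 6.70 to 6.79 differ. The other deposited table holds log2 values that the authors quantile normalized: a quantile normalization of the first table differs from it by a mean of at most 1.8e-08 and at most 0.000798 for any probe. How the authors made these values beyond that is not given in the sources used here. No detection p-value and no control probe label was used here, so whether a dim probe lies above background was not assessed.

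For the main analysis the log2 signals were returned to the linear scale, background-corrected by normexp with an offset of 50, quantile normalized and taken to log2 again, with limma 3.58.1 in R 4.3.3. The plan made before the data were examined preferred the neqc method and a filter on detection p-values, with this route and all probes as the stated fallback where those inputs are lacking. All 46237 probes were tested for a difference between groups with lmFit and eBayes (two-sided, Benjamini-Hochberg over all probes, adjusted p under 0.05), which called 4292 probes higher and 4769 lower. A fold change is IRF5-4D over control on this scale. The offset understates the fold change of dim probes, and probes near the top of the range can be saturated. Control signals of Ifnb1, Cxcl2, C1qb, Eomes and Il12b lay at or below percentile 25.9 of all probes, so the sizes of their rises are uncertain. The same holds for other genes with dim control signals, such as Hspa1a (percentile 30.2), Kit (36.1) and Il27 (44.3). Values are means ± SD over 3 arrays, and errors of fold changes are standard errors from the limma fit.

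Probes were named through the platform annotation, which gives 1 symbol for 35784 probes, several for 0 and none for 10453. Symbols were updated against the mouse RefSeq gene table (assembly GRCm38.p6, used for names and gene order only) through the gene identifier for 28620 probes and the accession for 2637, and 4527 kept the platform's symbol. This changed 937 symbols. Of the unnamed probes, 576 were higher and 692 lower. A gene was represented by its probe with the highest mean over the 6 arrays, which gave 21946 genes. Of 8521 genes with several probes, 38 had probes called in opposite directions, Cd8b1 among them. Axl, Bid, Cacna1h, Ccnd3, Cd44, Fosl2, H2-D1, Hbb-b1, Kit, Mdm2, Pgk1, Prdm1, Rplp0, Sqle, Tyms and Zap70 also have a probe that was not called. A further probe of 7 named genes was called in the same direction but differed by at least 2 log2 from the one used: Aldoc (-0.48 against -3.41), Cacna1h (-0.70 against -4.13), Cpeb3 (-1.64 against -4.06), Fosl2 (0.76 against 3.84), Hspa1a (0.41 and 1.05 against 3.23), Oasl2 (2.30 against 4.32) and Slc30a3 (1.96 against 6.98). Probe sequences were not used here, so cross-hybridisation between close paralogs was not checked.

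The genes named in the text were chosen by a rule set before the data were examined. It takes Irf5, the 10 highest and 10 lowest fold changes among called genes whose groups do not overlap (clone and model names left out), up to 4 called members of each gene list with the smallest adjusted p, and Il6, Tnf, Il12a, Il12b, Ifnb1, Ccl5, Cxcl10, Prdm1, Ikzf1, Irf4, Irf7, Pax5 and Bcl6 whatever their result; other genes of that part of the rule are not reported here. Where 5 or fewer members of a list were called in a direction, those outside the rule were named as well, and Lyz2, C1qa, Csf1r, Hba-a1, Cpa3 and Igh-6 were added as companions; these were chosen after their values were seen. The 29 gene lists were fixed in advance from general knowledge, and 546 of their 598 entries matched a measured gene. They were tested with camera (preset correlation of 0.01, two-sided, Benjamini-Hochberg over the lists), with an estimated correlation and the rotation test fry as alternatives. Camera compares a list with all other genes, and fry tests whether the genes of a list move one way on balance.

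Control and IRF5-4D samples share the replicate numbers 1 to 3 in the labels. The deviations of same-numbered samples from their group means correlated at 0.21, 0.17 and 0.27 across probes. Those of other pairs lay between -0.19 and -0.0003. Deviations from a group mean cancel out within each group, so positive values in same-numbered pairs push the others to negative values. The values of the other pairs are therefore not separate evidence of pairing. By the criterion set in advance, over 0.1 in every pair, the numbers were taken to pair the samples, and a fit with the replicate number as a block was run beside the planned fit without it. Counts, standard errors and adjusted p-values come from the planned fit, which leaves out this pairing, unless the block is named. No scan date or slide was used here, so batches beyond that were not tested.

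Alternatives were no background correction, median centring or cyclic loess in place of quantile normalization, the authors' normalized table, the replicate block, an intensity trend with a robust prior, array quality weights, averaging the probes of a gene, stricter thresholds (adjusted p under 0.01, or at least 2-fold), and leaving out each array in turn. A brightness filter and a normexp offset of 16 were added after the data were seen. The steps were tested on simulated data for the IRF5-4D against control comparison, with 21946 genes and known changes. There 31.8% of changes of 0.5 log2, 98.5% of 1 log2 and 100% of 2 log2 were recovered, and 8.88% of 169 probe calls were false. In this 1 simulated data set the false share was thus larger than the adjusted p threshold of 0.05 allows on average. The changes were placed only in probes above the median control level, about equally up and down, and in far fewer genes than were called in the real data. Noise was independent between probes and arrays. Recovery for dim probes, with many changed genes or with paired samples was therefore not measured. Figures were drawn with matplotlib 3.10.9.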

Results

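Gene expression was measured in mouse splenic B cells of the C57BL6/J strain after retroviral transduction. IRF5 is a transcription factor of the interferon regulatory factor family that acts downstream of Toll-like receptors, and IRF5-4D is, per the labels, a constitutively active variant of it. The control virus carried the vector with the cyan fluorescent protein marker but no IRF5-4D. Total RNA from 3 control samples and 3 IRF5-4D samples, described as biological replicates, was hybridised to 6 Illumina mouse WG-6 arrays with 46237 probes each. The median probe signal per array lay between 6.70 and 6.79 on the log2 scale, which is 104 to 111 brightness units. The design names 1 comparison, IRF5-4D virus against control virus, which asks which transcripts differ in B cells that carry the active variant. The number of arrays, 3 per group, limits the precision of every value.

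The arrays of one group resembled each other more than those of the other group. Pearson correlations across probes ranged from 0.991 to 0.993 within groups and from 0.938 to 0.955 between groups, and the first principal component, with 81.8% of the variance, separated the groups. Of 21946 genes, 2447 were higher and 2821 were lower with IRF5-4D, and 16678 were not called (limma, adjusted p under 0.05). The change was at least 2-fold in 974 of the higher and 952 of the lower genes, and at least 8-fold in 166 of the higher and 52 of the lower genes. The 3 arrays of one group lay entirely above or below those of the other for 2422 of the higher and 2781 of the lower genes, and for 34.9% of all genes, where chance gives 10%. The median log2 fold change over all genes was -0.01.

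**Figure D1:**
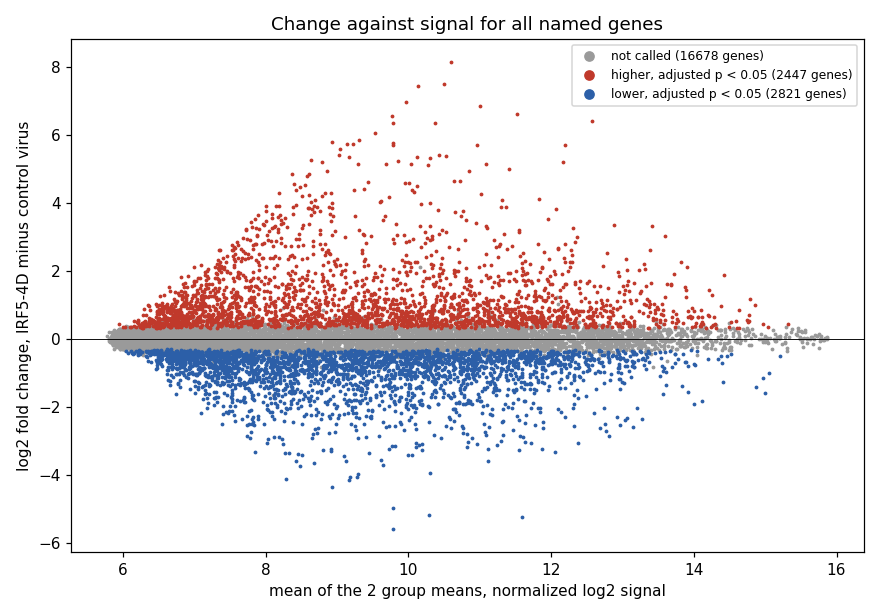
Log2 fold change of each named gene (IRF5-4D virus minus control virus, y axis) against the mean of both group means in normalized log2 signal (x axis); each point is 1 of 21946 genes, red for the 2447 higher and blue for the 2821 lower genes at adjusted p under 0.05, grey for the 16678 not called. The rises reach 8.14 (Trim54) and the falls reach -5.58 (Fcer2a).

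Mouse Irf5 was measured by 1 probe. Its signal was 11.62 ± 0.20 in the control arrays and 12.00 ± 0.15 in the IRF5-4D arrays (log2, mean ± SD, n = 3 each), a log2 fold change of 0.38 (SE 0.13; 1.30-fold) that was not called at an adjusted p of 0.0585. With the replicate number as a block, the same change had an adjusted p of 0.0167 and was called; it was also called without IRF5-4D replicate 2, at 0.46 with an adjusted p of 0.0430. All 3 IRF5-4D arrays lay above the 3 control arrays. Neither the species of the IRF5-4D insert nor whether the probe lies inside it is known here, so the value may be that of the endogenous gene alone and does not check the labels.

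The 10 named genes with the highest fold changes rose between 81-fold and 282-fold. Trim54, a muscle RING-finger protein, rose by 8.14 log2 (SE 0.14, 282-fold), followed by Slc26a4, the anion exchanger pendrin (7.51), the tight junction protein Cldn2 (7.44) and the zinc transporter Slc30a3 (6.98; its dimmer second probe gave 1.96, also called). The interferon-inducible antiviral protein Rsad2 rose by 6.85 (SE 0.15) and the inflammatory chemokines Ccl3 and Ccl4 by 6.62 and 6.41. The Ccl4 probe used reached 15.78 in the IRF5-4D arrays, near the top of the signal range, where a rise can be understated, and its less bright probe gave 7.46, so its size and rank are uncertain. The serine protease Htra4 rose by 6.56, Rapsn, which clusters acetylcholine receptors at the neuromuscular junction, by 6.35, and the receptor tyrosine kinase Axl by 6.34. The lowest fold change was that of Fcer2a, the low-affinity IgE receptor CD23 of mature B cells, at -5.58 (SE 0.29, 47.8-fold lower). The amino acid oxidase Il4i1 was at -5.24, the B-lineage protein Vpreb3 at -5.17 and lymphotoxin beta, Ltb, at -4.98 (SE 0.23, 31.6-fold lower). Rsph1 (-4.36), Srpk3 (-4.14), the calcium channel Cacna1h (-4.13), the atypical chemokine receptor Ackr2 (-4.07), Cpeb3 (-4.06) and Rnase6 (-3.99) completed the 10 lowest. The control signals of Trim54, Cldn2, Slc30a3, Htra4, Rapsn, Slc26a4, Axl and Rsad2 lay between the 38.8th and the 71.1st percentile of all probes. The IRF5-4D signals of the 10 lowest except Il4i1 lay between the 23.3rd and the 72.3rd percentile. Signal over background was not assessed there, so the sizes and ranks of these rises and falls are uncertain too. Adjusted p-values of these 20 genes were all at or below 1.76e-06, the value of Srpk3.

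Interferon-stimulated genes rose as a group. Of 40 measured, 36 were higher and 0 lower, also when adjusted over the list alone, and the median log2 fold change was 2.19. Besides Rsad2, the nucleotide kinase Cmpk2 rose by 4.93 (SE 0.17), the oligoadenylate synthetase-like gene Oasl2 by 4.32 (SE 0.16) and Irf7, the transcription factor that amplifies type I interferon production, by 4.01 (SE 0.15). The camera test against all other genes gave an adjusted p of 2.77e-31 with a preset correlation, and an adjusted p = 0.175 with an estimated correlation. None of the 16 lists called with the preset correlation was called with an estimated one. This held also for lists whose estimated correlation lay below the preset one, such as chemokines (-0.015). A call lost in this way does not by itself show that the genes of a list are correlated.

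Among cytokines, 14 of 29 measured genes were higher and 3 lower, with the same counts when adjusted over the list alone. Interferon beta, Ifnb1, went from 6.25 ± 0.01 to 9.92 ± 0.14 (log2, mean ± SD, n = 3 each), a rise of 3.67 or 12.7-fold (SE 0.11). Tnf rose by 3.75 (SE 0.16, 13.4-fold), Il6 by 2.94 (SE 0.17, 7.65-fold) and Il27, which encodes 1 subunit of interleukin 27, by 6.05 (SE 0.11). The probes of both subunits of interleukin 12 rose, Il12a by 1.90 (SE 0.31) and Il12b by 0.96 (SE 0.14). The Il12b probe lay at percentile 9.6 of all probes in the control and 63.7 in the IRF5-4D arrays. Signal over background was not assessed there, so whether this subunit was expressed is open. The 3 lower genes were Ltb, Csf2 (-0.72) and Tgfb1 (-0.80). The list had a median of 0.25 and a mean of 0.97 and was called higher (camera adjusted p of 1.66e-06; adjusted p = 0.191 with an estimated correlation). Il12a lost its call, at an adjusted p of 0.0664, when the spread was modelled with an intensity trend and a robust prior.

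Chemokines, the secreted attractants of leukocytes, followed the same direction. Of 22 measured, 10 were higher and 0 lower, and 13 were higher and 1 lower when adjusted over the list alone. Ccl5 rose by 5.71 (SE 0.18, 52.2-fold), Cxcl2 by 3.90 (SE 0.16) and Cxcl10 by 3.64 (SE 0.22). The median was 0.31, and the camera adjusted p was 9.65e-08 (adjusted p = 0.0506 with an estimated correlation). Receptors for chemokines and for homing were lower as a list, with 9 of 18 lower and 2 higher, also when adjusted over the list alone, and a median of -0.29. Ccr6 fell by 3.58 (SE 0.32) and the integrin subunit Itgb7 fell by 2.49 (SE 0.24), while Cxcr4 and Ccr7 rose by 1.14 (SE 0.10) and 1.51 (SE 0.18). Camera gave this list an adjusted p of 0.0273 (adjusted p = 0.228 with an estimated correlation).

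Lists of transcription factors and their targets differed in outcome. In the AP-1 family, dimeric factors induced by many stimuli, 10 of 13 genes were higher and 0 lower (11 and 0 when adjusted over the list alone), with a median of 0.89. Batf3 rose by 5.71 (SE 0.19), Fosl2 by 3.84 (SE 0.15), Jun by 3.08 (SE 0.16) and Atf3 by 2.86 (SE 0.16); the camera adjusted p was 5.91e-09 (adjusted p = 0.112 with an estimated correlation). The NF-kB pathway and its targets had 10 of 28 genes higher and 1 lower, also when adjusted over the list alone, and a median of 0.20. Gadd45b rose by 2.29 (SE 0.13), Ier3 by 1.44 (SE 0.15) and the NF-kB subunit Rela by 0.78 (SE 0.12), and Bcl3 fell by 0.93 (SE 0.11). The list was called higher (camera adjusted p of 0.0098; adjusted p = 0.456 with an estimated correlation), a call that ended without control replicate 2, at 0.0703, and with fry, at 0.0516. The IRF family was not called as a list (adjusted p of 0.158). Of its 8 measured genes, Irf7, Irf9 (1.43) and Irf2 (0.42) were higher, and Irf8 (-1.13) and Irf4 (-0.80) were lower. Adjusted over the list alone, 4 were higher, with Irf5 added, and 2 lower.

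Genes of B-cell identity fell. Of 28 measured, 19 were lower and 2 higher (20 and 2 when adjusted over the list alone), with a median of -1.14. Besides Fcer2a and Vpreb3, the surface protein Cd72 fell by 3.34 (SE 0.21, 10.1-fold lower), the B-cell transcription factor Spib fell by 2.67 (SE 0.15) and the lymphoid factor Ikzf1 fell by 1.12 (SE 0.14). Foxo1 (0.84) and the B-cell kinase Blk (0.93) were the 2 higher members. Pax5, the factor that maintains B-cell identity, was at 7.14 ± 0.13 in control and 7.15 ± 0.10 in IRF5-4D arrays, a log2 fold change of 0.01 (SE 0.11, adjusted p of 0.977). Its only probe lay at the 65.7th percentile of all probes in the control arrays, where the median probe level was 6.62 over all arrays. Signal over background was not assessed for this dim probe, so its unchanged value does not show that the Pax5 transcript was unchanged. The immunoglobulin mu constant region, listed under its older name Igh-6, was at 15.86 in both groups, at the top of the signal range, where a change can be masked. As a list, these genes had a camera adjusted p of 4.81e-09 (adjusted p = 0.288 with an estimated correlation). In the same arrays single markers of other cell types were higher, among them C1qb of macrophages (5.80), Batf3 of dendritic cells (5.71), Hdc of mast cells (5.14) and Hbb-b1 of red cells (3.36).

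Antigen presentation genes split by class. MHC class II presentation, which displays peptides to helper T cells, had 12 of 16 genes lower and 0 higher, also when adjusted over the list alone, with a median of -1.77. Ciita, the master regulator of class II genes, fell by 2.65 (SE 0.17, 6.28-fold lower), and the log2 fold changes of the lysosomal thiol reductase Ifi30, of H2-Ob and of H2-Eb2 were -3.02 (SE 0.21), -3.10 (SE 0.25) and -2.07 (SE 0.16). The class II list had a camera adjusted p of 8.8e-09 (adjusted p = 0.288 with an estimated correlation). MHC class I presentation had 14 of 18 genes higher and 0 lower (14 and 1 when adjusted over the list alone), with a median of 0.88. H2-Q7 rose by 2.25 (SE 0.13), H2-D1 by 1.87 (SE 0.10), the tapasin gene Tapbp by 1.80 (SE 0.11) and the peptide transporter Tap1 by 1.54 (SE 0.12). The class I list had a camera adjusted p of 1.72e-09 (adjusted p = 0.0506 with an estimated correlation). Class I genes are close in sequence, so their probes may share signal.

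**Figure D2:**
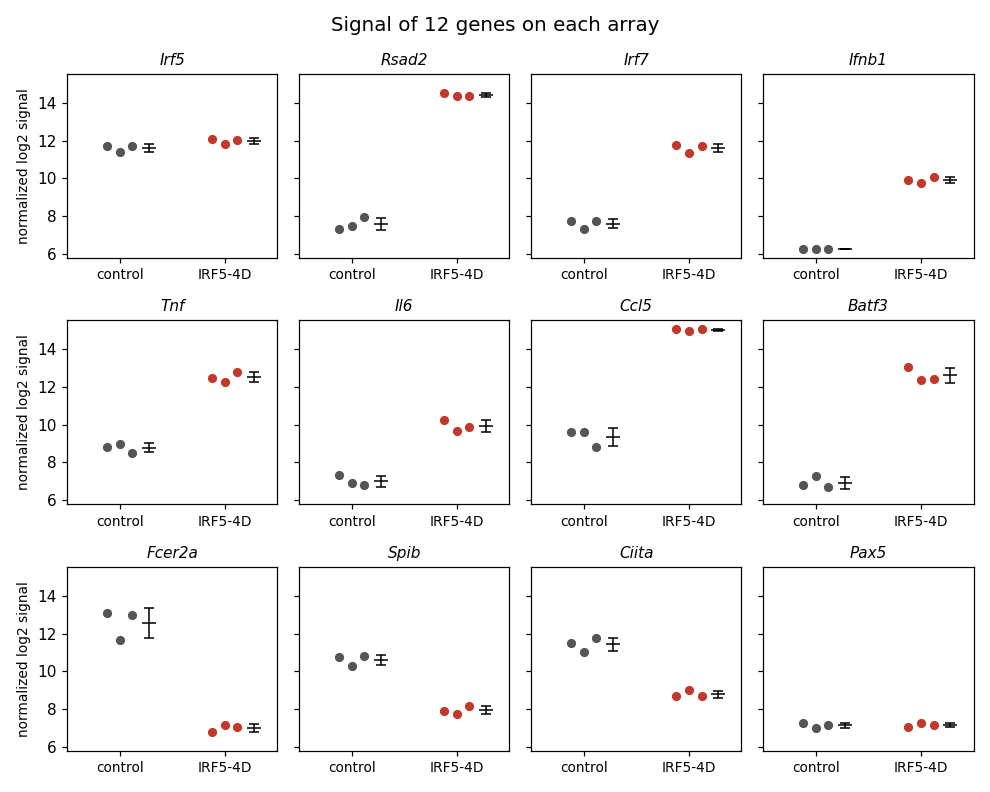
Normalized log2 signal (y axis) of 12 genes in each of the 3 control and 3 IRF5-4D arrays (points), with the group mean ± SD as a bar beside them. Rsad2, Irf7, Ifnb1, Tnf, Il6, Ccl5 and Batf3 are higher and Fcer2a, Spib and Ciita lower in all 3 IRF5-4D arrays, while Pax5, read by a dim probe, overlaps between the groups.

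Lists of B-cell differentiation and activation were not called in the main analysis. The plasma cell list had 11 of 26 genes lower and 2 higher (12 and 3 when adjusted over the list alone), with a median of -0.21, and was not called (camera adjusted p of 0.105). Prdm1, which encodes Blimp-1, the driver of plasma cell differentiation, fell by 1.25 (SE 0.15, 2.37-fold lower), as did Slpi (-2.33, SE 0.16), Fkbp11 (-1.97, SE 0.24) and Irf4 (-0.80, SE 0.12), while the chaperones Hspa5 (0.86) and Pdia6 (0.73) were higher. The list was called lower without control replicate 1 (adjusted p of 0.0275), without IRF5-4D replicate 3 (0.0190) and with median centring in place of quantile normalization (0.0373). The germinal centre list was not called (adjusted p of 0.158), with 1 of 13 genes higher and 5 lower, also when adjusted over the list alone. Bcl6, the repressor that maintains germinal centre B cells, rose by 1.69 (SE 0.19, 3.23-fold), while Mef2b (-3.12, SE 0.35), Plxnb2 (-1.29), Neil1 (-1.02), Ung (-0.68) and S1pr2 (-0.50) were lower. B-cell activation markers were not called as a list (adjusted p of 0.938), with 3 of 23 genes higher and 6 lower (4 and 6 when adjusted over the list alone). Egr2 (3.99, SE 0.23), Cd44 (1.91, SE 0.12) and Tnfrsf8 (1.30) were higher, and Slamf1 (-3.36, SE 0.19) and the BAFF receptor Tnfrsf13c (-2.17, SE 0.16) were among the lower genes.

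The Toll-like receptor pathway had 7 of 19 genes higher and 6 lower (7 and 7 when adjusted over the list alone) and was not called (adjusted p of 0.916). Irak2 rose by 1.85 (SE 0.16) and Tlr2 by 1.80 (SE 0.19), while Cd180 (-3.45, SE 0.18) and Tlr1 (-2.90, SE 0.17) were lower. Among apoptosis regulators, 8 of 26 were higher and 8 lower (9 and 8 when adjusted over the list alone). The caspases Casp8 and Casp4 rose by 1.63 (SE 0.10) and 1.71 (SE 0.14), and the pro-apoptotic genes Bid (-1.90, SE 0.15) and Bmf (-2.34, SE 0.19) were lower. This list was not called (adjusted p of 0.501), and its median was 0.14 where its mean was -0.01. The p53 target list was not called (adjusted p of 0.395), with 3 of 19 genes higher and 6 lower (4 and 7 when adjusted over the list alone). Mdm2 (1.64, SE 0.10), Cdkn1a (1.70) and Plk3 (0.87) were the higher members, and Trp53inp1 (-1.74, SE 0.11), Sesn1 (-1.93, SE 0.18) and Zmat3 (-1.65, SE 0.18) were among the lower ones.

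Cell cycle genes were called higher as a list with a small shift. Of 35 measured, 10 were higher and 1 lower, also when adjusted over the list alone, and the median was 0.16. Tyms rose by 1.60 (SE 0.16), Ccnd3 by 1.40 (SE 0.13) and Cdc20 by 0.87 (SE 0.15), and the transcription factor E2f2 fell by 1.28 (SE 0.13). The camera adjusted p was 0.00581 (adjusted p = 0.538 with an estimated correlation), and the call ended without control replicate 3, at 0.0734, and with fry, at 0.141. Unfolded protein and amino acid stress genes had 5 of 19 higher and 0 lower (6 and 0 when adjusted over the list alone), with a median of 0.28. Ddit3 rose by 2.25 (SE 0.21), Ppp1r15a by 1.98 (SE 0.13), Cebpb by 1.96 (SE 0.28), Trib3 by 1.91 (SE 0.49) and Aars1 by 0.71. The camera adjusted p was 0.00434 (adjusted p = 0.538 with an estimated correlation), and this call also ended without control replicate 3, at 0.0734, and with fry, at 0.139. Trib3 itself lost its call without IRF5-4D replicate 1 (1.67, adjusted p of 0.0625) and with an intensity trend and robust prior (adjusted p of 0.251). Its control signals were 12.18, 11.56 and 9.56 in replicates 1, 2 and 3, so control replicate 3 carried much of its rise. Heat shock genes, which encode protein-folding chaperones, had 7 of 13 higher and 0 lower (8 and 0 when adjusted over the list alone), with a median of 0.60. Hspa1a rose by 3.23 (SE 0.20), Hspa1b by 1.23 (SE 0.12), Bag3 by 1.13 (SE 0.15) and Dnajb1 by 0.68 (SE 0.13), with a camera adjusted p of 5.91e-05 (adjusted p = 0.191 with an estimated correlation).

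Metabolic lists were lower. For cholesterol synthesis, 9 of 13 genes were lower and 0 higher (10 and 0 when adjusted over the list alone), with a median of -1.12. Dhcr7 fell by 1.81 (SE 0.17), and Mvd (-1.72, SE 0.20), Sqle (-1.46, SE 0.18) and Sc5d (-1.35, SE 0.12) were lower too, and the camera adjusted p was 4.12e-06 (adjusted p = 0.289 with an estimated correlation). For glycolysis, 7 of 15 genes were lower and 1 higher (9 and 1 when adjusted over the list alone), with a median of -0.31. Aldoc fell by 3.41 (SE 0.19), Pgam1 (-0.93, SE 0.21), Hk1 (-0.69, SE 0.12) and Pgk1 (-0.55, SE 0.13) were also lower, and Pfkp (0.65) was higher. The camera adjusted p was 0.0161 (adjusted p = 0.478 with an estimated correlation), and the call ended without control replicate 2, at 0.0719. Pgk1 lost its call when its probes were averaged, at -0.11 with an adjusted p of 0.663. Ribosomal protein genes were not called as a list (adjusted p of 0.916), with 1 of 17 lower, Rplp0 at -0.86 (SE 0.15), and 0 higher, also when adjusted over the list alone. Their median was 0.03 and their mean -0.05.

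**Figure D3:**
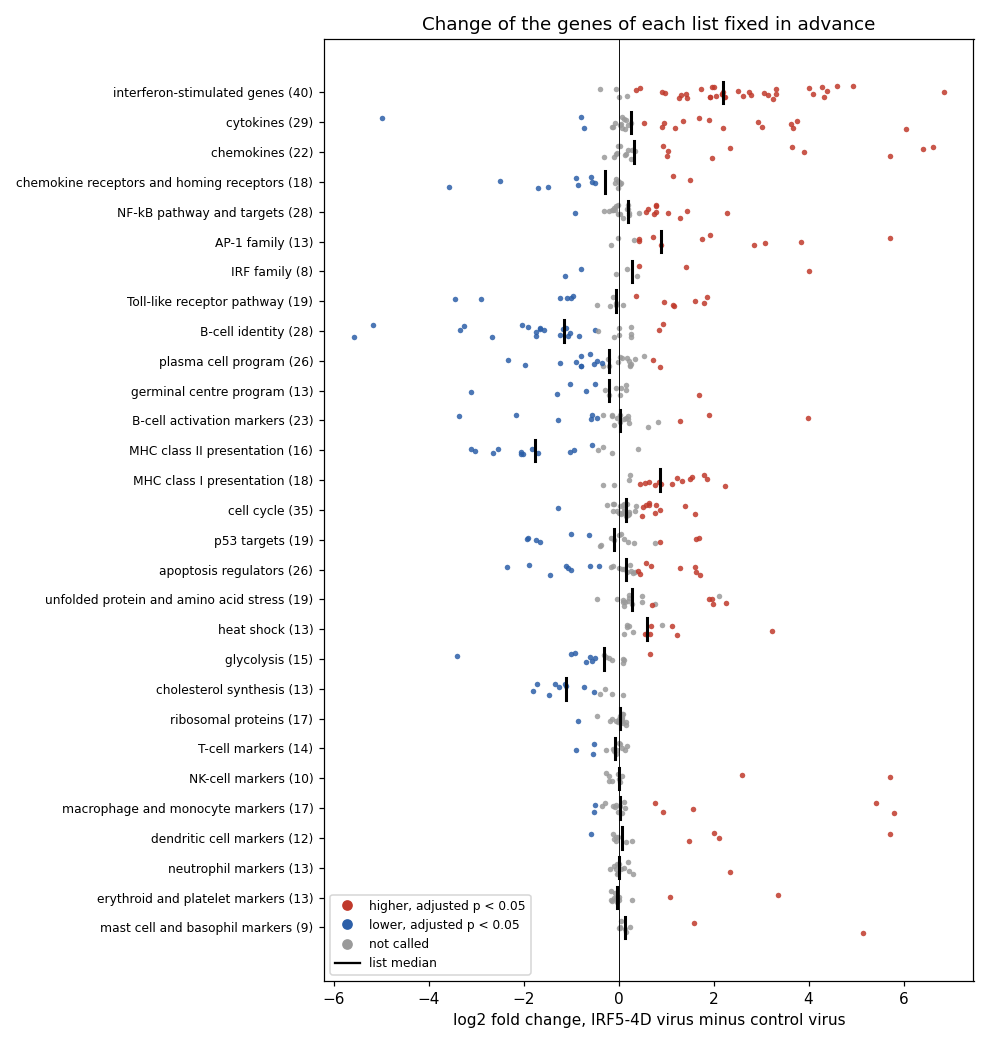
Log2 fold change (x axis, IRF5-4D virus minus control virus) of each measured gene in 29 lists fixed before the data were examined, with the number of measured genes in brackets on the y axis; red and blue points were higher and lower at adjusted p under 0.05, grey points were not called, and the black bar is the list median. Interferon-stimulated genes have the highest median, 2.19, and MHC class II presentation the lowest, -1.77; points are spread vertically within a list only for visibility.

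Markers of other cell types that a spleen culture could hold were measured as 7 further lists. In each of them most genes were not called, and the list medians lay between -0.08 and 0.13. Macrophage and monocyte markers were not called (adjusted p of 0.116), with 5 of 17 higher and 2 lower (5 and 3 when adjusted over the list alone). The complement subunit C1qb rose by 5.80 (SE 0.14) and the Fc receptor chain Fcer1g by 5.42 (SE 0.18), followed by Mpeg1 (1.56, SE 0.17), Adgre1 (0.93) and C1qc (0.77, SE 0.12), while Cd68 (-0.51) and Tyrobp (-0.49) were lower. The log2 fold changes of the third C1q subunit C1qa, of lysozyme Lyz2 and of Csf1r were -0.12, 0.10 and 0.14, none of them called. Dendritic cell markers were called higher (camera adjusted p of 0.0287; adjusted p = 0.289 with an estimated correlation), with 4 of 12 higher and 1 lower, also when adjusted over the list alone. These were Batf3, Cst3 (2.11, SE 0.13), the interferon-stimulated Bst2 (2.01, SE 0.23) and Zbtb46 (1.49, SE 0.17), against Xcr1 at -0.59. Mast cell and basophil markers were called higher with 2 of 9 higher and 0 lower, also when adjusted over the list alone. Hdc, which makes histamine, rose by 5.14 (SE 0.30) and the receptor Kit by 1.58 (SE 0.13), and Cpa3 was at 0.05 without a call. The camera adjusted p of this list was 0.0300 (adjusted p = 0.289 with an estimated correlation), and the call ended without control replicate 3 (0.0883), without IRF5-4D replicate 1 (0.0567) and with probes averaged (0.117).

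The other 4 of these lists were not called. Erythroid and platelet markers (adjusted p of 0.460) had 2 of 13 higher and 0 lower, also when adjusted over the list alone: Hbb-b1 at 3.36 (SE 0.20) and Ppbp at 1.09 (SE 0.15), with Hba-a1 at -0.17 without a call. NK-cell markers (adjusted p of 0.460) had 2 of 10 higher and 0 lower, also when adjusted over the list alone, namely Ccl5, which is shared with the chemokine list, and Eomes (2.60, SE 0.25). Neutrophil markers (adjusted p of 0.460) had 1 of 13 higher and 0 lower, also when adjusted over the list alone. This was Lcn2 at 2.35 (SE 0.47), which lost its call with an intensity trend and robust prior (adjusted p of 0.150). T-cell markers (adjusted p of 0.358) had 0 of 14 higher and 3 lower, also when adjusted over the list alone: Cd28 (-0.89, SE 0.18), Cd8b1 (-0.54, SE 0.15) and Zap70 (-0.52, SE 0.15). The other 2 probes of Cd8b1, both dimmer, were higher, at 1.41 and 3.11. Cd8b1 lost its call without control replicate 2 (adjusted p of 0.0648) and without IRF5-4D replicate 1 (0.0762). Zap70 lost its call when control replicate 1 (0.145) or 3 (0.0898) or IRF5-4D replicate 2 (0.0729) or 3 (0.114) was left out.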

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

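Alternatives were planned before the data were seen, except the brightness filter and the normexp offset of 16. Of 120 named genes measured, 113 kept their direction and their side of the threshold under every alternative in which they were tested. The stricter thresholds were not applied to single named genes. Called genes that changed less than 2-fold, such as Rela (0.78) and Irf4 (-0.80), would not pass the threshold of at least 2-fold. The brightness filter left out named genes with a dim probe, such as Il12b. The counts of genes, 2447 higher and 2821 lower, stayed within 1.5 times under each alternative except the threshold of at least 2-fold, which left 974 higher and 952 lower because it is stricter by construction. Leaving out each array in turn gave 2125 to 2365 genes higher and 2429 to 2601 lower, 8 to 11 lists higher and 4 to 6 lower, and 0.26 to 0.46 for Irf5. The replicate block gave 2770 genes higher and 3128 lower. It made Irf5 a call (0.38, adjusted p of 0.0167) and changed no other call among the named genes and lists. With an estimated correlation camera called 0 lists higher and 0 lower, against 11 and 5 with the preset one. For chemokines, chemokine and homing receptors and MHC class I presentation, the estimated correlation was -0.015, -0.016 and -0.0026, below the preset one. Their camera adjusted p nevertheless rose, to 0.0506, 0.228 and 0.0506. This argues against a higher correlation as the cause for these lists. The other called lists had estimates above the preset one. Since calls were lost without a higher estimate too, their loss cannot be put down to correlation alone, and the cause was not tested. The test fry, which asks another question, called 13 and 7: it lost NF-kB (adjusted p of 0.0516), cell cycle (0.141) and unfolded protein stress (0.139), and it gained the IRF, macrophage, NK-cell, neutrophil and erythroid lists as higher and the germinal centre and T-cell lists as lower. Cd8b1 reversed to 1.32 with probes averaged, since its dimmer probes rose, and it lost its call with an offset of 16 (adjusted p of 0.0525). Macrophage and monocyte markers became a call with the brightness filter (0.0220), and the cause was not tested. The median fold change of all genes moved by less than 0.1 under every scaling. Each scaling brings the arrays to a common level, so this value could not show a shift shared by most genes. The neqc route and both other detection filters were not run because they need detection p-values or control probes, so signal over background was not assessed for dim probes; median centring and cyclic loess followed normexp instead.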

Other observations

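The tests on other cell types, on the share of B cells, on scaling and on dim probes, and the gene families, were chosen only after the results were seen; the neighbour test and the splits of the arrays were planned before.

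Gene families that were not planned as lists were also counted. Immunoglobulin variable segments fell together: of 23 measured, 22 were lower and 0 higher, with log2 fold changes from -3.07 (Igkv3-4) to -0.28 (Igl-V1, not called and near the top of the signal range) and a median of -2.30. The camera adjusted p over 11 families was 1.9e-23 (adjusted p = 0.187 with an estimated correlation). Probes of variable segments are close in sequence and may share signal, so 22 is not a count of independent genes. Of 13 class I-like H2-Q and H2-T genes, 8 were higher and 0 lower, led by H2-Q8 (2.62) and H2-T10 (2.57), with a camera adjusted p of 2.21e-06 (adjusted p = 0.187 with an estimated correlation). H2-Q1, H2-Q7 and H2-T23 are also in the planned class I list, so this family partly repeats it.

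Of 9 schlafens, 3 were higher, with Slfn1 at 5.73 (camera adjusted p of 0.0111; adjusted p = 0.187 with an estimated correlation). Of 28 claudins, the tight junction proteins, 5 were higher and 1 lower, with Cldn23 at 3.91, Cldn4 at 2.53 and Cldn7 at 1.62 beside Cldn2, and the family was not called (0.0603). Of 28 killer lectin-like receptors, 3 were higher, Klra17 (5.35), Klrb1f (4.58) and Klrg2 (2.50), again without a call of the family (0.122). Ifitm3 and Ifitm1, which restrict virus entry, rose by 4.25 and 3.77 while the other 5 measured members of that family were not called (family 0.219). Among 11 PARP genes 5 were higher, led by Parp12 (3.42), and 2 lower, Parp1 (-1.43) and Parp16 (-0.57), and the family was not called (0.189); Parp14 is also in the planned interferon list. Of 79 histone genes 15 were higher and 5 lower (camera adjusted p of 0.0111; adjusted p = 0.471 with an estimated correlation). As families, sialyltransferases (4 of 20 genes higher, 5 lower), the GIMAP family (2 of 7 higher, 3 lower) and solute carriers (39 of 356 higher, 49 lower) were not called.

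The first pattern is that single markers of other cell types rose. More cells of such a type would bring its other markers too, so the share that rose by 1 log2 or more was counted among each list's dim members (control mean below the 75th percentile of probes), together with any brighter member that rose. It was 18.8% of 16 macrophage and monocyte markers (exact binomial 95% upper bound 45.6%), 33.3% of 12 dendritic cell markers (65.1%), 22.2% of 9 mast cell and basophil markers (60.0%) and 22.2% of 9 NK-cell markers (60.0%), each below the 75% set for such cells, with genes that are not independent. These values argue against newly added cells that carry most markers of a list as the whole source, although a probe that fails to detect its transcript would look alike. The 75% was set after the values were seen. The dendritic cell list and the mast cell and basophil list join kinds of cell that need not share most markers. Added cells of 1 such kind are therefore not decided. Of the 15 dim macrophage markers 4 were called higher (C1qb 5.80, Fcer1g 5.42, Adgre1 0.93 and C1qc 0.77) and 1 lower (Tyrobp -0.49). Risers that were bright in the controls already, namely Hbb-b1, Mpeg1, Bst2, Cst3 and Ccl5, leave open more cells of types that the controls hold: over the 7 lists 62.5% of 8 bright members rose (upper bound 91.5%), too few to decide. Of 13 erythroid and platelet markers counted as above, 15.4% rose (upper bound 45.4%), and Hba-a1 was at -0.17 without a call. This goes against newly added cells that carry most of these markers as well. Red cells nevertheless stay open, since Hbb-b1 already lay at the 92.7th percentile in the controls and Hba-a1 only at percentile 25.2: if the control signal of Hbb-b1 came from red cells, the dim probes did not show them there and would not need to show more of them. A candidate explanation that stays open is expression of these genes by the transduced B cells themselves, as is a kind of cell outside these lists; neither was tested.

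The second pattern is the fall of B-cell identity and MHC class II genes. If cells of the 6 listed other types without red cells and platelets had replaced B cells, most markers of at least 1 type would rise, but the highest share, counted in the same way, was 33.3% (dendritic cells, upper bound 65.1%), below the 75% set for such cells. Replacement by 1 kind of cell that carries only part of a list is not decided by this share. Camera nevertheless called the dendritic cell (adjusted p of 0.0287, mean 0.90) and the mast cell and basophil list (0.0300, mean 0.82) higher. With an estimated correlation neither was called (adjusted p = 0.289 for both), and the mast cell call also ended without control replicate 3 (0.0883), without IRF5-4D replicate 1 (0.0567) and with probes averaged (0.117). The test fry called all 7 lists but the T-cell list higher, so small additions stay possible, as does partial replacement by red cells or an unlisted kind of cell. A lower share of B cells alone would lower their genes by a common amount. Of 28 B-cell identity genes, however, 19 were lower, 2 higher and 7 not called. Fcer2a (-5.58, SE 0.29), Cd72 (-3.34, SE 0.21) and Spib (-2.67, SE 0.15) fell by unlike amounts. These values argue against a lower share as the whole source, though dim or saturated probes could blur this. The scaling between arrays is argued against as the source, since the median of both lists together was -1.20 and came no nearer to 0 than -1.15 under the other scalings. A change in the transduced B cells, the explanation the design offers, was not tested.

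The third pattern is that large rises started from dim probes more often than large falls ended there. Of 166 genes that rose at least 8-fold, 62 (37.3%) had a control mean below the median probe level of 6.62, while of 52 that fell at least 8-fold, 5 (9.62%) had an IRF5-4D mean below it (Fisher's exact test, two-sided, p of 0.000112, with genes that are not independent). Background correction and normalization could stretch dim probes, so genes, calls and dim levels were taken anew from the deposited signal, without either step. There 55 of 150 risers (36.7%) started below the median level of 6.74 and 5 of 51 fallers (9.80%) ended below it (Fisher's exact test, two-sided, p of 0.000173), which argues against stretching in these steps as the main source. The control levels of these genes may lie below detection, which leaves the size of the fold changes open.

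Neighbouring genes often changed in one direction, a hypothesis that position on the chromosome matters. Among 1443 pairs of neighbouring called genes with different name stems, out of 18844 genes placed, 63.4% changed in the same direction, against 50.2% with directions shuffled (permutation test, 100000 resamples, one-sided p of 1e-05, the smallest they can give). Duplicated genes with unlike names and probes that read through into a neighbour were not separated, so shared position and shared sequence stay open as sources.

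The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. In 1 of the 10, the real one, limma called 5268 genes, and the highest count of the other splits was 0 at an adjusted p under 0.05, with 308 to 734 genes at an unadjusted p under 0.05. Every other split has both viruses in each group, so the IRF5-4D difference adds to the spread within groups. Few gene calls there were therefore fixed in advance by the design. Camera called 16 lists in the real split, again the highest in 1 of the 10, and 1 to 11 in the other splits. The split with 11 is one of those that part all 3 pairs of numbered samples as the real split does. Because the other splits keep a part of the IRF5-4D difference, they do not give a rate of false calls. For the same reason, the lists called where 0 genes were called do not show whether the preset correlation calls too many lists. List calls near the threshold still need caution, since several of them ended when 1 array was left out.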
